A study of Arabidopsis thaliana with 4 samples.

How the data were processed

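Small RNA was sequenced from mature pollen of 4 Arabidopsis lines, 1 library per line: wild-type Columbia-0 or the dcl2/dcl4 double mutant, each with a reporter under the KRP6 promoter that carried either a miR173 site or a mock site. Plants grew side by side in long days, and pollen was collected from open flowers into a sucrose buffer, per the labels' protocols. RNA was extracted with TRIzol, the 17 to 29 nt fraction was taken from a gel, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. The deposited files list each distinct tag of 18 to 28 nt with its raw read count, a whole number that was not normalized, seen from the values. The genome build TAIR10 is named per the submitters' processing notes; the aligner, the adapter trimmer and their versions are not given in the sources used here. Each of the 3180752 distinct tags had an exact match in the reference, so the files hold genome-matched tags.

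Tags were matched without mismatches to the TAIR10.1 nuclear, mitochondrial and plastid sequences with Python 3.11.15 and numpy 2.4.6. Tags that matched rRNA, tRNA, snRNA or snoRNA genes, ribosomal DNA with 7000 nt on either side, or an organelle were left out, because their level follows RNA breakdown. They made up 62.9%, 72.5%, 67.8% and 74.2% of reads in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site. The remaining reads were assigned to 36901 annotated features and to windows of 500 nt on the 5 nuclear chromosomes, and a tag with several loci was divided equally among them. Values are in RPM, reads scaled by the nuclear reads without structural RNA. One floor of 3 counts stands for 0.881, 1.72, 1.10 and 4.68 RPM in the same order of libraries. A fold against 0 counts is computed with it, which is not the limit of its counting interval.

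Values of single libraries carry exact Poisson 95% intervals, ratios of 2 libraries exact conditional binomial intervals and shares Wilson intervals, computed with scipy 1.17.1. Changes over all 4 libraries were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM, filterByExpr) in an additive model of genotype and transgene with 1 residual degree of freedom, on sums rounded to whole counts, with Benjamini-Hochberg adjustment at 0.05. Standard errors were approximated from the log2 fold change and the F statistic. The TMM factors were 1.12, 0.995, 0.956 and 0.943. Pearson's r of log2 counts scaled by library size across 13132 features, which are not independent replicates, was 0.912 between both mock-site libraries, 0.876 between both wild-type libraries, 0.819 between both dcl2/dcl4 libraries and 0.719 between both miR173-site libraries. The median of a list was placed among 10000 random lists drawn from the 100 features on either side in mean abundance. A percentile therefore compares a list with features of like abundance and not with 0, and it treats members that share tags as independent. Figures were drawn with matplotlib 3.10.9.

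The statistics were tested on simulated data in which 200 features changed. The simulation gave all features 1 common dispersion (0.0905, and 0.103 for windows) and purely additive effects, so its rates need not hold for the real data. Changed features lost to the low-count filter were left out of the rates. AT1G77880, with 237 and 216 reads in wild type and 0 in both mutants, was not called in the main fit. For genotype over 12120 features, 27 of 89 at 4-fold (30.3%) and 80 of 88 at 16-fold (90.9%) were recovered with 0 false calls. For transgene over 12136 features, 43 of 89 at 4-fold (48.3%) and 86 of 86 at 16-fold were recovered with 9 false calls. For genotype over 27848 windows, 30 of 83 at 4-fold (36.1%) and 73 of 81 at 16-fold (90.1%) were recovered with 0 false calls.

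The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where stated. Named were members of the fixed lists with an adjusted p under 0.05 and 2 to 4 of the most abundant members of each list, the 10 features or 5 windows per direction with the largest change past 0.05 and a mean of 10 RPM, the 10 most abundant MIR genes, and up to 5 features per direction in comparisons of single libraries with 50 or more tags in 1 library, a ratio of 4 or more and counting intervals that do not overlap. The lists were miR173-triggered TAS, other TAS, DCL4-dependent young MIR, 22-nt trigger MIR, pollen-enriched MIR, conserved MIR, secondary-siRNA PPR genes, auxin receptor and NLR targets, targets of TAS and 21-nt miRNA, RNA silencing genes, the transgene promoter locus, transposable element classes, plastid genes and structural RNA. The lists of photosynthesis genes and pollen transcripts, MIR822 and TAS3 by size, the KRP6 block (depth of 5 or more, gaps up to 150 nt) with its 3 alternatives and the annotation classes were chosen after the files were seen. The transposable element classes could not be separated, because only 37 features carry such a word in this annotation, and they were pooled. The word search also took in genes that are not transposons, such as ADC1, HTA9, CMT3 and UBP1B, and these were left in the list as found.

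Alternatives were DESeq2 1.42.0 with its size factors, all genome-matched tags or MIR tags as library size (both without TMM), no filter on low counts, tags with 1 locus only, 21-nt and 22-nt tags only, 24-nt tags only, the tested factor alone, and each library left out in turn. With 3 libraries the model of both factors has 0 residual degrees of freedom, so the tested factor alone was fitted there, and the lone library of a group was assumed to vary like the others. Sizes were recounted by distinct tags, with all tags, with tags of 1 locus and without MIR genes, and TAS levels were recomputed per all tags, per MIR tags, with 1 mismatch and for 21-nt and 22-nt tags. The comparison of small RNAs from the reporter sequence was planned and left out, because it needs tags without a match in the Arabidopsis genome and 0 reads lacked one.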

Results

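Small RNAs of mature pollen of Arabidopsis thaliana were sequenced in 4 libraries, 1 for each combination of 2 genotypes and 2 transgenes. The genotypes were wild-type Columbia-0 and a double mutant of DCL2 and DCL4, the Dicer-like enzymes that process double-stranded RNA into 22-nt and 21-nt small interfering RNAs (siRNAs). Both transgenes placed a truncated green fluorescent protein sequence under the promoter of KRP6, a gene for an inhibitor of cyclin-dependent kinases. One carried a 22-nt site for the microRNA miR173, the trigger of trans-acting siRNAs, and the other a 22-nt mock site that no small RNA targets. The libraries held 9169478 reads in wild type with the mock site, 6333684 in dcl2/dcl4 with the mock site, 8465251 in wild type with the miR173 site and 2488459 in dcl2/dcl4 with the miR173 site. After tags of structural RNAs and organelles were left out, 3404390, 1744215, 2722503 and 641441 nuclear reads remained in the same order, and values are given in RPM, reads scaled by these totals. Ribosomal RNA took 51.6%, 60.3%, 61.1% and 62.8% of all reads, the mitochondrion 9.72%, 11.2%, 4.62% and 10.05%, and transfer RNA 0.0192%, 0.0150%, 0.0190% and 0.0161%. There were no replicates within a group. The 95% intervals and the floors of 3 counts therefore cover counting error of reads only. The reads carry no molecular identifiers, so copies of 1 molecule cannot be told from separate molecules, and the intervals may be too narrow. Comparisons of single libraries have no replicate check and no p-value.

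The mutated genes were examined first. DCL2 gave 2.64, 3.44, 4.41 and 3.12 RPM and DCL4 gave 5.97, 5.16, 7.35 and 6.24 in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site, respectively. These were 2 to 12 reads at DCL2 and 4 to 20.3 at DCL4. Tags at a gene do not measure its messenger RNA, and few tags lay there, so these values check the genotype labels very little.

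The first comparison set the sizes of pollen small RNAs in dcl2/dcl4 beside those in wild type. The ends of the size range differed between libraries. Tags of 18 nt held 2.16% in wild type and 2.16% in dcl2/dcl4 with the mock site, and 5.36% and 3.35% with the miR173 site. Those of 28 nt held 0.111%, 0.388%, 0.0252% and 2.03% in the same order. Whether the gel fraction moved the shares below was not tested. The 22-nt class was smaller in dcl2/dcl4 in both transgene backgrounds. It held 15.3% of nuclear tags in wild type and 10.7% in dcl2/dcl4 with the mock site, a difference of -4.59 percentage points (95% interval -4.65 to -4.53). With the miR173 site it held 13.3% and 8.86%, a difference of -4.49 points (-4.57 to -4.41). The 21-nt class held 21.4% and 21.6% in the mock-site pair (0.137 points, 0.0617 to 0.212) and 25.6% and 21.6% in the miR173-site pair (-4.01 points, -4.12 to -3.89). The small mock-site difference turned negative under each alternative count, for example to -2.32 points without MIR genes. The 24-nt class, made by DCL3, held 20.6% and 25.6% with the mock site (4.98 points, 4.90 to 5.06) but 22.2% and 20.8% with the miR173 site (-1.38 points, -1.49 to -1.27). The first difference was -0.106 points over all genome-matched tags, and the second was 1.31 points when each distinct tag was counted once.

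**Figure D1:**
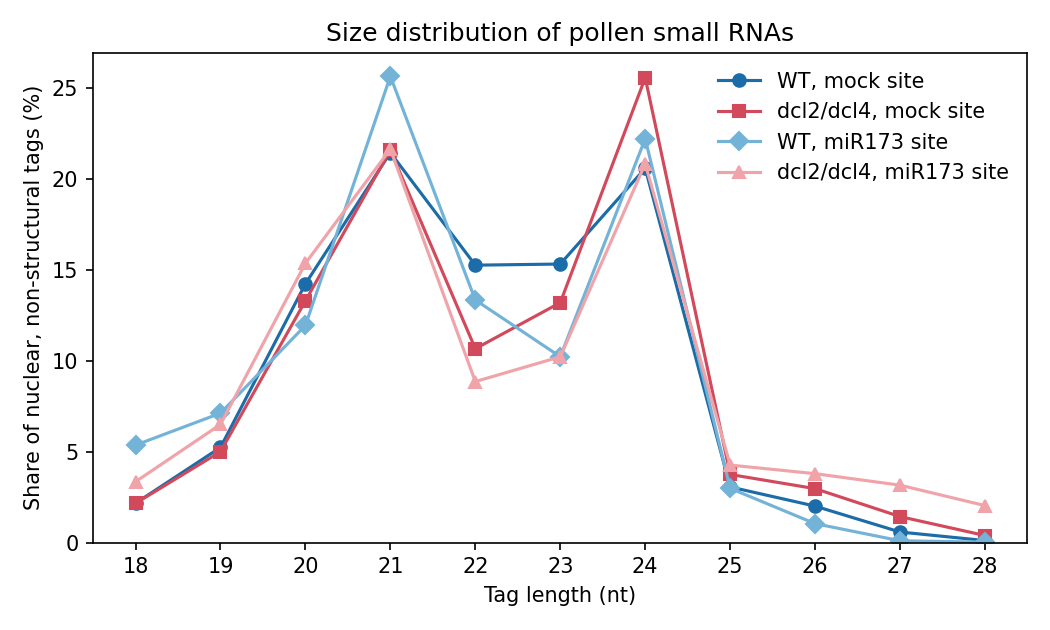
The share of nuclear tags without structural RNA, in percent, is plotted against tag length in nt, with 1 line for each of the 4 libraries. At 22 nt both dcl2/dcl4 libraries (10.7% and 8.86%) lie below both wild-type libraries (15.3% and 13.3%).

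The largest group of 22-nt tags, and most of the difference, lay outside annotated features. There, 22-nt tags numbered 84410 RPM in wild type and 46564 in dcl2/dcl4 with the mock site, a ratio of 0.552 (0.547 to 0.556), and 67979 and 35665 with the miR173 site, a ratio of 0.525 (0.517 to 0.532). At pseudogenes the 22-nt ratios were 0.646 (0.636 to 0.656) and 0.516 (0.501 to 0.531). Antisense to protein-coding genes they were 0.644 (0.630 to 0.660) and 0.453 (0.433 to 0.474). On the sense strand of protein-coding genes they were 1.08 (1.06 to 1.09) and 1.09 (1.08 to 1.11), above 1 by less than the scaling moves them. Scaling to all tags in the file instead shifted every ratio of dcl2/dcl4 to wild type by -0.43 log2 with the mock site and -0.32 with the miR173 site, and scaling to MIR tags by -0.32 and 0.19.

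Trans-acting siRNAs (tasiRNAs) were compared between the genotypes. They are processed mainly by DCL4 from TAS transcripts after cleavage by a microRNA, and the miR173-triggered TAS genes are TAS1A, TAS1B, TAS1C and TAS2. In the miR173-site lines, 21-nt tags at these genes numbered 5599 RPM in wild type and 1123 in dcl2/dcl4, 4.99-fold lower (4.63 to 5.38). In the mock-site lines they numbered 8548 and 6866, 1.25-fold lower (1.22 to 1.27). Tags of 24 nt were higher in both dcl2/dcl4 libraries, at 554 and 1109 RPM with the mock site (ratio 2.00, 1.88 to 2.13) and 548 and 1146 with the miR173 site (2.09, 1.91 to 2.28). These directions held when counts were scaled to all tags or to MIR tags. The 24-nt tags set the mock-site dcl2/dcl4 library apart from both wild-type libraries, and whether its mutant genotype is the one on the label was not tested.

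TAS1C, the most abundant TAS gene (chromosome 2, 16537288 to 16538277 in TAIR10.1), had 21-nt levels of 5788 and 4907 RPM in wild type and dcl2/dcl4 with the mock site, and of 4035 and 797 with the miR173 site (5.07-fold lower, 4.63 to 5.55). TAS2 (chromosome 2, 16539384 to 16540417) had 21-nt levels of 1803 and 1229 with the mock site and of 1096 and 182 with the miR173 site (6.01-fold lower, 4.99 to 7.29). Of the 21-nt tags downstream of miR173 cleavage at TAS1C, 63.1%, 63.6%, 73.1% and 52.0% lay in its 21-nt register, where chance gives 4.76%. The order is wild type and dcl2/dcl4 with the mock site, then wild type and dcl2/dcl4 with the miR173 site. At TAS2 the shares were 41.5%, 41.9%, 27.4% and 33.3%, and at TAS1B 56.2%, 54.9%, 43.8% and 43.6%. At TAS1A they were 30.9%, 30.7%, 42.5% and 21.6%. The last library had only 117, 55 and 37 such tags at TAS2, TAS1B and TAS1A. At TAS1C, 24-nt tags downstream lay in register at 10.7%, 6.20%, 10.7% and 3.99%. The miR173 site of TAS1C lies at 16537890 to 16537911 and pairs with 2 mismatches.

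**Figure D2:**
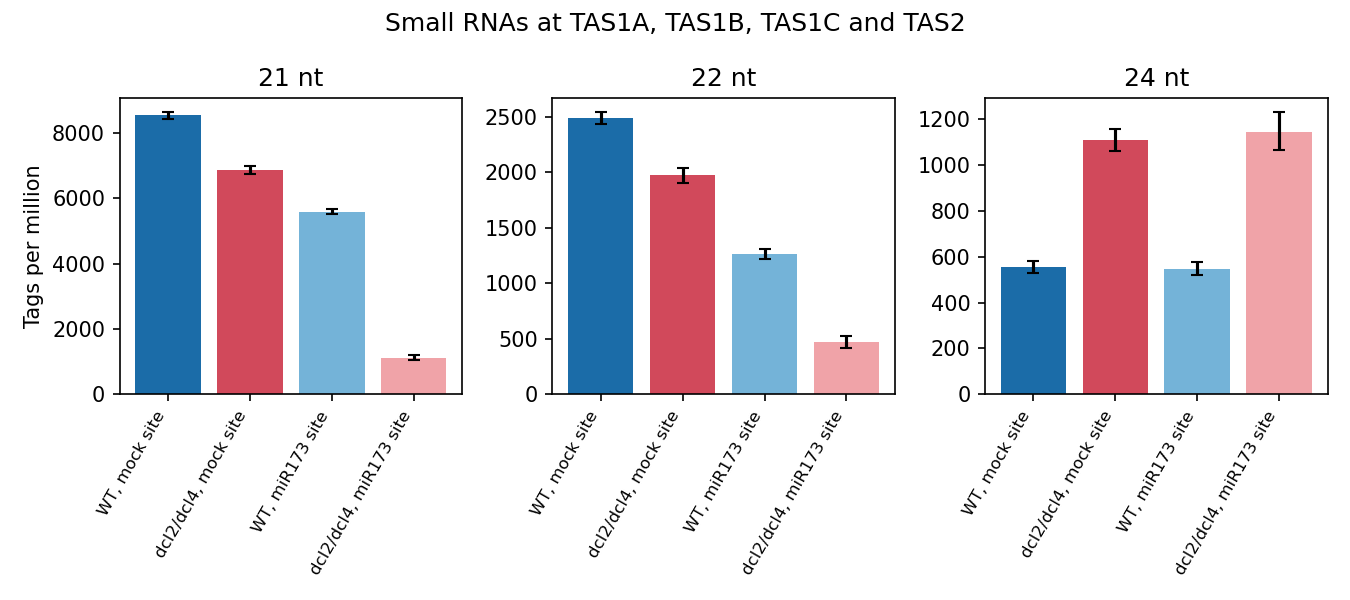
Bars give tags in RPM at the miR173-triggered TAS genes together, for tags of 21, 22 and 24 nt in the 4 libraries, with 95% Poisson intervals. The 21-nt level is 1123 in dcl2/dcl4 with the miR173 site and 6866 in dcl2/dcl4 with the mock site, and the 24-nt level is 1146 and 1109.

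Other DCL4 products were also lower in dcl2/dcl4. The other TAS genes had 21-nt levels of 187 and 95.2 RPM with the mock site and 303 and 48.3 with the miR173 site in wild type and dcl2/dcl4. TAS3, the source of the tasiRNAs against auxin response factors, had 140 and 77.4 with the mock site (1.81-fold lower, 1.49 to 2.20) and 233 and 39.8 with the miR173 site (5.75-fold lower, 3.88 to 8.86). The secondary-siRNA PPR genes, pentatricopeptide repeat genes that tasiRNAs target, had 21-nt levels of 499 and 337 with the mock site (1.48-fold lower, 1.35 to 1.63) and 339 and 98.7 with the miR173 site (3.46-fold lower, 2.68 to 4.53). MIR822, a young MIR gene processed by DCL4, had 44, 9, 40 and 0 reads of 21 nt in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site. It was 2.50-fold lower (1.21 to 5.84) in the first pair and 3.14-fold lower against the floor in the second. Its 24-nt tags were 2.06-fold (1.26 to 3.37) and 4.95-fold (2.13 to 11.7) higher in dcl2/dcl4.

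The 4 libraries were then fitted together, with both factors in 1 model. Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13132 features changed with genotype at an adjusted p of 0.05, 1597 had an unadjusted p under 0.05 where chance gives 657, and DESeq2 called 9. The smallest adjusted p was 0.184 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 31958 windows of 500 nt, edgeR called 0, with 4255 at an unadjusted p under 0.05 where chance gives 1598, and DESeq2 called 56. The 2 libraries of a genotype carry different transgenes, and nothing in the labels says that libraries came from separate cultures. With both factors fitted, each p-value tests the effect of 1 factor against an error term. That term comes from departure from additive effects of genotype and transgene, with information shared across features, and not from spread among replicates. Taking only tags with 1 genomic locus gave 126 features and fitting genotype alone gave 60. With 1 library left out, where genotype alone was fitted too, the count was 28 to 384, so it depends on these choices. Taking all genome-matched tags as library size, without TMM, moved the median log2 fold change of all features from -0.00 to -0.33, and list medians below are relative to the former.

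All 13 tested members of the secondary-siRNA PPR genes had a negative log2 fold change for dcl2/dcl4 against wild type, with a median of -1.34 that lay below those of all 10000 random lists matched on abundance. Members that share tags, which were divided equally among their loci, do not move independently, and the random lists do not copy this. AT1G63150 (chromosome 1, 23419294 to 23421714) had -1.38 ± 0.52 (approximate SE), AT1G62910 had -1.51 ± 0.50, AT1G63080 had -0.75 ± 0.46 and AT1G63130 had -1.76 ± 0.54. None of the 13 passed over all features in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0 passed adjusted over the list alone. With tags of 1 locus only, the same test called AT1G63130 lower over all features (-2.23, adjusted p 0.0141). All 4 miR173-triggered TAS genes were also negative, with a median of -0.80 (percentile 2.30 of random lists), from -0.76 ± 1.03 at TAS1C and -0.78 ± 0.58 at TAS1A to -1.37 ± 0.83 at TAS2, and 0 passed over all features or adjusted over the list alone.

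Among the other TAS genes, all 3 tested were negative (median -0.90, percentile 5.69). TAS3b had -1.92 ± 0.52 and was the 1 member that fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment when adjusted over the list alone (adjusted p 0.0183), and 0 passed over all features. TAS3 had -0.90 ± 0.55 and TASIR-ARF -0.10 ± 0.56. All 3 DCL4-dependent young MIR genes were negative (median -0.57, percentile 23.3), with -0.57 ± 0.45 at MIR839, -1.10 ± 0.53 at MIR869 and -0.06 ± 0.37 at MIR822, and 0 passed over all features or adjusted over the list alone.

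On average over the 4 libraries the most abundant MIR genes were MIR165a at 17194 RPM, MIR165b at 15957, MIR158a at 15176, MIR166a at 10447 and MIR403 at 8222, followed by MIR166b, MIR166f, MIR166c, MIR166d and MIR166g between 7724 and 7765. In wild type with the miR173 site the order among these genes differed, with MIR166a at 20560 and MIR158a at 15871. MIR166b, MIR166f, MIR166c, MIR166g and MIR166d followed between 14214 and 14275, ahead of MIR165a at 11119. Members of the MIR165 and MIR166 families share tags, so their separate values are uncertain. MIR165a had 0.72 ± 1.26 for dcl2/dcl4 against wild type and MIR166a -0.56 ± 1.20. Of 64 conserved MIR genes tested, 28 were higher and 36 lower (median -0.37, percentile 0). The percentile compares them with features of like abundance and not with 0, and members that share tags are not independent. Among its own random lists the median of 0.84 of the pollen-enriched MIR genes lay only at percentile 55.3. The summed tags of the conserved MIR genes were higher in dcl2/dcl4 with the mock site (ratio 1.25, 1.25 to 1.26, and 0.929 per all tags). They were lower with the miR173 site (0.798, 0.792 to 0.804). MIR408 (-3.18, adjusted p 0.0233) and MIR169e (-2.84, adjusted p 0.0241) fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment when adjusted over the list alone, where 0 passed over all features. Over all features MIR408 was called lower with DESeq2, tags of 1 locus and genotype alone, and MIR169e with the last 2, and neither was with 21-nt and 22-nt tags or 24-nt tags. Of the 4 tested 22-nt trigger MIR genes, 2 were higher and 2 lower (median -0.30). MIR393a had -1.92 ± 0.52 and fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment when adjusted over the list alone (adjusted p 0.0220), where 0 passed over all features. Of 10 pollen-enriched MIR genes tested, 9 were higher (median 0.84, percentile 55.3), such as MIR158b at 0.81 ± 0.94 and MIR845b at 1.26 ± 0.73, and 0 passed over all features or adjusted over the list alone.

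In the remaining lists no member passed for genotype over all features or adjusted over the list alone. The auxin receptor and NLR targets had 1 higher and 3 lower (median -0.49), with -1.19 ± 0.45 at AFB2. The targets of TAS and 21-nt miRNA had 2 higher and 2 lower (median 0.04, -0.28 with all genome-matched tags as library size), with -0.70 ± 0.48 at AGO1. The RNA silencing genes had 3 higher and 5 lower (median -0.17), with 0.33 ± 0.52 at AGO2. The transposable element classes, 37 features found by class words, which also took in genes that are no transposons such as ADC1, HTA9 and CMT3, had 25 tested, with 6 higher and 19 lower (median -0.50, percentile 0.120), with -0.57 ± 0.44 at SADHU8-1. KRP6, the transgene promoter locus, had -0.54 ± 1.29. The photosynthesis genes had 6 higher and 9 lower (median -0.07), and all 9 pollen transcripts were higher (median 0.99, percentile 56.4), with 1.12 ± 0.86 at VGD1.

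Signs of carried-over tissue and of transcript fragments differed between libraries beside these groups. Tags of the plastid chromosome, the marker fixed for other flower tissue, made up 0.309%, 0.173%, 0.312% and 0.269% of reads in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site. Sense tags of the 15 photosynthesis genes numbered 1516, 845, 1042 and 1898 RPM, and those of the 9 pollen transcripts 12374, 20386, 8647 and 23128.

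Comparing single libraries, 35 of 5106 features were lower and 7 higher by 4-fold or more in dcl2/dcl4 with the mock site than in wild type. The lower features were led by AT5G42410 (85.6-fold, 15.1 to 3399) and AT1G77880 (40.5-fold against the floor, at least 32.7-fold by its counting interval). Next came SAG12, a senescence-associated cysteine protease gene (30.4-fold, 10.2 to 149), AT5G46295 (27.2-fold, 4.67 to 1093) and MIR169e (10.6-fold, 4.00 to 39.9). In the order named they had 1, 0, 3, 1 and 4 reads in dcl2/dcl4 with the mock site. Only a count of 0 was set to the floor, so 1 read can give a larger fold than 0 reads, and this order is uncertain. The higher ones were led by AT5G57130 (22.9-fold, 10.6 to 58.7), AT4G29920 (19.8-fold, 8.61 to 56.2), AT2G32291 (16.3-fold, 6.97 to 46.4), IRX15 (7.03-fold, 3.91 to 13.4) and MGH3, a histone H3 gene of the male gametes (5.38-fold, 3.66 to 8.07). In the miR173-site pair AT5G57130 went the other way, at 4.59 RPM in wild type and 1.56 in dcl2/dcl4. AT4G29920 had 4.5 and 2 reads there, and AT2G32291, IRX15 and MGH3 were higher in dcl2/dcl4 there too. With the miR173 site 450 of 4196 features were lower and 108 higher. The cut of 50 tags is met at a lower RPM in the deeper library, here wild type (2722503 against 641441 nuclear reads). It favours lower features here and, less so, in the mock-site pair (3404390 against 1744215), so counts per direction are not comparable. The lower ones were led by ARP9 (36.3-fold, 9.96 to 301), AT1G09500 (33.7-fold, 5.95 to 1340), AT1G22120 (29.7-fold, 5.23 to 1182), DOX1 (28.3-fold, 4.98 to 1126) and AT3G43130 (24.3-fold, 4.26 to 968). They rested on 2, 1, 1, 1 and 0.833 reads in dcl2/dcl4, fewer than the floor of 3 counts, so their folds and order are uncertain. The higher ones were led by the pseudogene AT4G03750 (15.6-fold, 13.2 to 18.4), AT4G13230 (15.1-fold, 9.90 to 23.6), MIR5026 (11.9-fold, 8.07 to 17.9), the pseudogene AT2G01037 (11.4-fold, 10.2 to 12.8) and AT3G51070 (11.1-fold, 6.74 to 18.8).

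The second comparison concerned the transgenes, whose question was whether a miR173 site sets off secondary siRNAs from the reporter in pollen. Every tag matched the nuclear or organelle reference genome exactly and 0 reads lacked a match, so siRNAs of the reporter sequence itself were not analysed here. The trigger was present in all libraries. The 22-nt miR173 (TTCGCTTGCAGAGAGAAATCAC, chromosome 3, 8236161 to 8236182) had 89, 52, 13 and 9 reads, or 26.1, 29.8, 4.78 and 14.03 RPM, in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site. Most tags of MIR173 came from the other arm, where the 21-nt tag at 8236223 to 8236243 reached 323, 411, 92.6 and 270 RPM.

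Tags over the KRP6 promoter were most abundant in wild type with the mock site. In the 1500 nt upstream of KRP6 (chromosome 3, 6617952 to 6619451; the gene lies at 6616330 to 6617951 on the minus strand), wild type with the mock site had 313 RPM (294 to 332), against 2.87 (0.931 to 6.69) in dcl2/dcl4 with the mock site, 2.57 (1.03 to 5.30) in wild type with the miR173 site and 17.1 (8.56 to 30.7) in dcl2/dcl4 with the miR173 site. That was 109-fold higher (46.6 to 337) than in dcl2/dcl4 with the same site and 122-fold higher (58.8 to 303) than in wild type with the miR173 site. The 22-nt tags numbered 361, 0, 0 and 0 reads in the same order of libraries as above. Tags formed a block of 1590 nt (6617712 to 6619301) that held 1554 reads in wild type with the mock site, of which 46.2% (43.7 to 48.7) were antisense to KRP6, 68.4% (66.0 to 70.7) lay upstream of the gene and 30.5% were 22 nt long. The same block held 38 reads in dcl2/dcl4 with the miR173 site (59.2 RPM, 41.9 to 81.3), of which 57.9% (42.2 to 72.1) were antisense. The KRP6 gene itself had 148, 18.3, 7.35 and 42.1 RPM. In wild type with the mock site its tags lay mostly in the part of the block inside the gene. Mean depth there was 69.3 reads from 6617800 to 6617849, against 0.48 from 6617000 to 6617049 outside the block. Because the promoter is present in the transgene and at the gene, the tags of the block could have come from either copy.

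**Figure D3:**
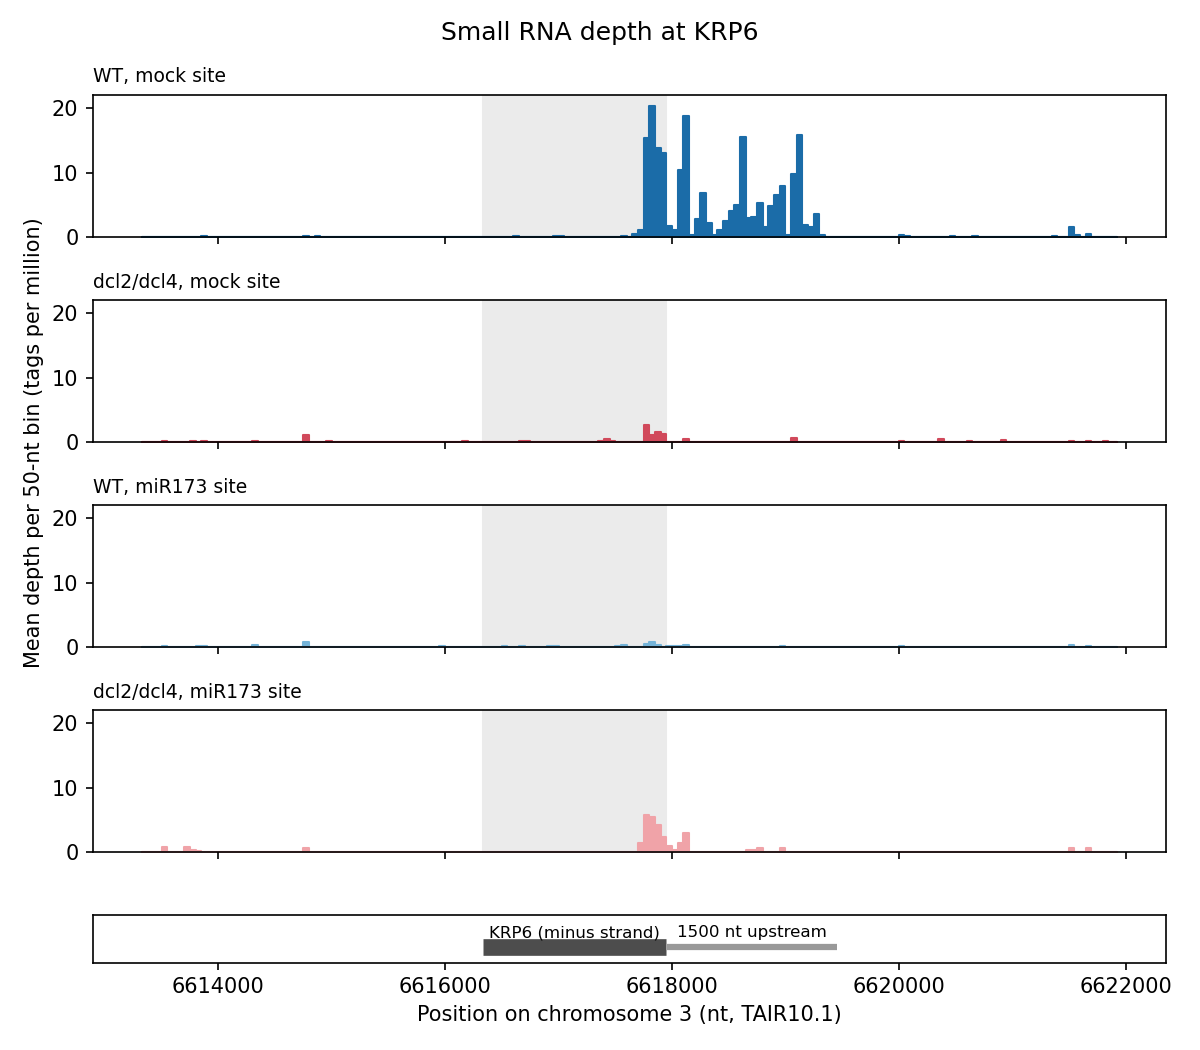
Mean small RNA depth in 50-nt bins, in RPM, is plotted along chromosome 3 around KRP6 for the 4 libraries, with the gene shaded and the 1500 nt upstream drawn below. The block from 6617712 to 6619301 stands out in wild type with the mock site, at 456 RPM against 17.8, 6.61 and 59.2 in the other libraries.

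Endogenous small RNAs were also compared between the transgenes. The miR173-triggered TAS genes had lower values with the miR173 site, with log2 fold changes from -1.06 ± 1.03 at TAS1C to -1.46 ± 0.83 at TAS2 and a median of -1.22 (percentile 0.0200), and all 13 secondary-siRNA PPR genes were negative (median -0.90), and in both lists 0 passed over all features or adjusted over the list alone. The conserved MIR genes had 38 higher and 26 lower (median 0.20, percentile 100, but -0.15 with MIR tags as library size), the 22-nt trigger MIR genes 3 higher and 1 lower (median 0.71), and the pollen-enriched MIR genes 4 higher and 6 lower (median -0.08), and 0 passed in any of these either way. With tags of 1 locus only, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called MIR156h higher (2.64, adjusted p 0.0327) and MIR156b lower (-2.56, adjusted p 0.0379). Summed tags of the 22-nt trigger MIR genes went the other way from their median. Their ratios of the miR173 site to the mock site were 0.683 in wild type and 0.897 in dcl2/dcl4. KRP6 had -1.62 ± 1.29. Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 13132 features changed, 1118 had an unadjusted p under 0.05 and DESeq2 called 0. Fitting the transgene alone also gave 0 on all 4 libraries, and 4, 0, 0 and 812 when wild type with the mock site, dcl2/dcl4 with the mock site, wild type with the miR173 site or dcl2/dcl4 with the miR173 site was left out. Taking MIR tags as library size, without TMM, moved the median of all features to -0.36.

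Some members passed when adjusted over the list alone. Lower with the miR173 site was MIR839 (-1.45 ± 0.46, adjusted p 0.0373), and higher were TASIR-ARF (1.85 ± 0.53, 0.0232), AGO5 (2.00 ± 0.56, 0.0283) and AGO9 (2.31 ± 0.59, 0.0283), Argonaute genes of the germline, all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over their own lists, while over all features 0 passed, and with tags of 1 locus AGO9 did. The DCL4-dependent young MIR genes had 1 higher and 2 lower (median -0.27), the other TAS genes 3 higher (median 0.28, but -0.05 with MIR tags as library size), the RNA silencing genes 5 higher and 3 lower (median 0.29, but -0.18), the auxin receptor and NLR targets 3 higher and 1 lower (median 0.24, but -0.11), the targets of TAS and 21-nt miRNA 2 higher and 2 lower (median -0.06, but 0.02 by DESeq2) and the transposable element classes 7 higher and 18 lower (median -0.18). All 15 photosynthesis genes were higher (median 0.25, but -0.09 with MIR tags as library size) and 8 of 9 pollen transcripts lower (median -0.13), and 0 passed over all features or adjusted over the list alone in these last lists.

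Between single wild-type libraries 158 of 5582 features were higher and 18 lower by 4-fold or more with the miR173 site. The higher ones were led by MIR397b (28.8-fold, 12.0 to 90.3), AT2G25905 (19.4-fold, 7.20 to 73.4), MIR159c (16.9-fold, 14.9 to 19.3), the thionin gene THI2.1 (16.6-fold, 7.75 to 42.5) and ARPN (16.3-fold, 5.98 to 61.9). The lower ones were led by KRP6 (20.1-fold, 12.9 to 33.2), whose tags in the mock-site library lay mostly in the promoter block. Next came MIR156e (7.59-fold, 7.10 to 8.13), the long non-coding RNA AT3G05955 (7.59-fold, 6.17 to 9.42), MIR156b (7.57-fold, 7.09 to 8.09) and MIR156f (7.54-fold, 7.05 to 8.07). Tags shared among MIR156 genes were divided equally between them, so these 3 values are not independent and their intervals leave out that uncertainty. In dcl2/dcl4, 16 of 2714 features were higher, led by AT4G13230 (16.5-fold, 9.81 to 29.4), AT2G04115 (11.7-fold, 6.33 to 23.3), AT3G28770 (9.66-fold, 7.36 to 12.8), AT3G51070 (9.60-fold, 5.53 to 17.5) and AT1G52680 (9.19-fold, 5.58 to 15.8). Another 59 were lower, led by AT5G57130 (30.2-fold, 5.26 to 1205), ARP9 (18.4-fold, 4.96 to 154), AT4G29920 (11.2-fold, 2.97 to 94.7), AT3G28922 (10.3-fold, 3.91 to 38.4) and AT2G03930 (8.83-fold, 2.90 to 43.8). These lower ones had 1, 2, 2, 4 and 3 reads with the miR173 site. AT5G57130 and AT4G29920 were named above from the same mock-site mutant library. ARP9, AT4G13230 and AT3G51070 were named above from the same miR173-site mutant library. Their ratios here are therefore not independent of those between the genotypes. In both genotypes the mock-site library was the deeper one, so the cut of 50 tags favours features lower with the miR173 site.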

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

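Of the tests below, those of reads shared with another locus and of green tissue were set before their values were seen, and the others were chosen only after the result was seen, as was setting the plastid share beside the photosynthesis genes.

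The 21-nt tags of the miR173-triggered TAS genes had a ratio of dcl2/dcl4 to wild type of 0.803 with the mock site (0.596 per all tags, 0.644 per MIR tags) and 0.200 with the miR173 site (0.161 and 0.229), and those of the other TAS genes 0.509 and 0.160. A wild-type library with the wrong label was argued against by 24-nt tags at the miR173-triggered TAS genes, which stood at 1109 RPM against 554 and 548 in wild type. Scaling as the whole source of the difference between the mutant libraries was argued against by the ratio of 21-nt to 24-nt tags at these genes, which was 6.31-fold higher (5.64 to 7.07) in the mock-site than in the miR173-site mutant. Wild-type reads mixed into the library were argued against as the whole source by 26 windows with less than 1 read in the other mutant library. Together they held 27.1% of the wild-type mock-site level, with an upper limit of 30.1%, below the 80.3% of the 21-nt tags. Single windows were unlike, with 1 read against 264 in wild type with the mock site (from 6988001 on chromosome 3) and 45 against 80.5 (from 1349501 on chromosome 2). AT1G77880, picked from these windows after its value was seen, had 0 reads against 237 in wild type with the mock site. By its counting interval that was at most 0.0306 of the wild-type level. An admixture within these bounds, a mutant genotype of that line other than its label says, and a biological difference between the mutant lines may remain and were not tested. The values of the mock-site library as a dcl2/dcl4 library are therefore open to doubt.

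Upstream of KRP6, tags were 0.00916 of the wild-type level in dcl2/dcl4 with the mock site and 6.67 times it with the miR173 site, and the difference between these ratios was not tested. Breakdown of the KRP6 transcript was argued against by 46.2% antisense tags, and reads shared with another locus by 100% of the block's tags having 1 genomic locus. The transgene copy of the promoter and the copy at the gene cannot be told apart, since tags running into vector sequence would be needed and 0 tags without a genome match were present. With 1 line per group, an effect of that line was not separated from one of genotype or site.

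Single MIR genes, picked after their values were seen, went both ways between the wild-type libraries: with the miR173 site MIR159c was 16.9-fold higher and MIR166a stood at 20560 against 5778 RPM, while MIR156e, which shares tags with other MIR156 genes, was 7.59-fold lower and MIR403 stood at 4014 against 8001. Whether RNA of green tissue contributed was not settled. Sense tags of photosynthesis genes were 1042 RPM there, 1516 in wild type with the mock site and up to 1898 in another library, but this baseline could hide a small share, and the plastid share, the marker fixed beforehand, was 0.312% against 0.309%, 0.173% and 0.269%. Size selection towards shorter RNA was argued against as the whole source, because 21-nt tags of MIR159a were 5.39-fold higher (5.14 to 5.64) than in wild type with the mock site while 21-nt tags of MIR165a were lower, at 10269 against 13735 RPM. Tags of 18 nt made up 5.36% in wild type with the miR173 site against 2.16% with the mock site, so size selection may still have contributed. Other tissue was not tested.

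Other values had opposite signs in the 2 transgene backgrounds as first counted, and none of these differences was tested. The share of 21-nt tags differed by 0.137 points (mock site) and -4.01 points (miR173 site) between dcl2/dcl4 and wild type, and that of 24-nt tags by 4.98 and -1.38 points. The 21-nt signs were alike under all 4 other counts, where the mock-site difference was -2.10, -2.27, -1.53 and -2.32 points, and the 24-nt signs were alike over all tags (-0.106 and -2.69) and by distinct tags (5.95 and 1.31). Conserved MIR tags had ratios of 1.25 (0.929 per all tags) and 0.798 over all sizes, 1.32 (0.982 per all tags) and 0.787 at 21 nt, and 1.37 and 0.570 at 22 nt. Tags of 24 nt at transposable element classes had ratios of 1.23 (0.916 per all tags) and 0.717, and photosynthesis genes 0.554 and 1.79.

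Among tags outside the main measurement, shares of all tags differed between the transgenes in both directions. With the miR173 site over the mock site, rRNA had ratios of 1.18 in wild type and 1.04 in dcl2/dcl4, snRNA 1.66 and 1.56, and snoRNA 1.23 and 1.20. Plastid tags had ratios of 1.01 in wild type and 1.56 in dcl2/dcl4, tRNA 0.993 and 1.07, and the mitochondrion 0.476 and 0.896.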

How the results depend on the processing

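The alternatives for the KRP6 region were chosen after seeing the data; all others were set before the data were examined. Where all genome-matched tags or MIR tags were the library size, TMM was left out as well. With genotype, edgeR called 0 features, and also 0 with all genome-matched tags as library size or 24-nt tags. It called 47 features (15 higher, 32 lower) with MIR tags as library size and no TMM, 127 without a filter, 126 with tags of 1 locus, 6 with 21-nt and 22-nt tags and 60 with genotype alone, and DESeq2 called 9. Each fit without 1 library held the tested factor alone, so it is set beside that factor alone on 4 libraries, and the low-count filter was applied anew. Against 60 features with genotype alone, there were 384 without wild type with the mock site, 187 without dcl2/dcl4 with the mock site, 28 without wild type with the miR173 site and 87 without dcl2/dcl4 with the miR173 site, where the lone library was assumed to vary like the others. For windows the count of 0 became 101 with MIR tags, 265 without a filter, 23 with tags of 1 locus and 56 with DESeq2, and with genotype alone it was 0 on 4 libraries and 1490, 1517, 236 and 256 without 1 library, in the order above. With the transgene 0 features became 2 with MIR tags, 37 without a filter and 16 with tags of 1 locus, and with the transgene alone there were 0 on 4 libraries and 4, 0, 0 and 812 without 1 library. The cause was not tested.

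Of the size classes, the 22-nt difference was negative under every alternative run. With the mock site it was -4.17 points by distinct tags, -2.01 with all tags, -4.76 with tags of 1 locus and -5.01 without MIR genes, and with the miR173 site -4.23, -2.60, -4.44 and -5.79. The 21-nt difference with the mock site reversed to -2.10, -2.27, -1.53 and -2.32, and with the miR173 site was -2.89, -6.62, -1.74 and -3.02. The 24-nt difference with the mock site was 5.95, -0.106 (reversed), 5.05 and 6.92, and with the miR173 site 1.31 (reversed), -2.69, -4.38 and -2.51. The cause was not tested. The log2 ratio of tasiRNAs, -0.26 with the mock site and -1.38 with the miR173 site, was -0.69 and -1.70 per all tags, -0.58 and -1.19 per MIR tags and -0.32 and -2.11 for 21-nt and 22-nt tags, and stayed within its interval with 1 mismatch. The KRP6 ratios stayed within theirs under all 3 alternatives.

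The 4 other settings for small RNAs of the reporter were not run in either of its comparisons, for want of tags without a genome match. No paired analysis was possible beyond the additive model, which already compares genotypes within each transgene with 1 residual degree of freedom, because each group holds 1 library. Depth limits dcl2/dcl4 with the miR173 site most, where 641441 nuclear reads put the floor at 4.68 RPM.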

Other observations

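The loci in this part were chosen after their values were seen. In the 3000 nt upstream of MGH3 (chromosome 1, 6901963 to 6904962), a histone H3 gene of the male gametes, small RNAs were higher in both dcl2/dcl4 libraries. They numbered 5.87 RPM in wild type and 169 in dcl2/dcl4 with the mock site (28.8-fold, 18.3 to 47.8), and 2.20 and 234 with the miR173 site (106-fold, 47.6 to 294). The 24-nt tags upstream of MGH3 were 3.23, 82.0, 0 (floor 1.10) and 133 RPM in wild type and dcl2/dcl4 with the mock site and wild type and dcl2/dcl4 with the miR173 site. At MGH3 itself the levels were 10.9, 58.8, 7.35 and 53.8.

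AT1G77880 (chromosome 1, 29285902 to 29287190) had 237 and 216 reads in wild type with the mock site and the miR173 site and 0 in both dcl2/dcl4 libraries. Against the floor that was 40.5-fold lower with the mock site (at least 32.7-fold by its counting interval) and 17.0-fold lower with the miR173 site. In wild type its tags were 27.3 and 18.4 RPM at 22 nt and 11.5 and 21.3 at 21 nt.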
